A study of Mus musculus with 2 samples.

How the data were processed

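Chromatin accessibility was measured in single live cells of mouse heart non-myocytes, the cells of the heart other than its muscle cells. Per the labels, cells that excluded the dye 7-AAD were sorted by flow cytometry from wild-type C57BL/6 hearts at 10 to 12 weeks of age, and libraries were made with the Chromium Single Cell ATAC v1.0 kit. The series holds 2 libraries of 1 group, named replicate 1 and replicate 2 here. The labels do not say whether they come from separate animals. The p-values of genes and regions below therefore measure only how class differences vary between these 2 libraries. The p-values of gene lists set the genes of a list against the other genes, so neither kind measures a spread between animals. Per the submitters' processing notes, the tools used were FastQC, Cell Ranger and Cell Ranger ATAC 1.1.0, with genome build mm10. The notes do not say how regions were called or how barcodes were chosen.

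The deposited values are counts per region and barcode that the authors capped at 1, so each value is 0 (closed) or 1 (open), with no scaling. All values of both libraries were checked, and 0 of them were anything other than 0 or 1. Both libraries use the same 162126 regions in the same order, with a median width of 518 bp. Replicate 1 holds 5181 barcodes with 41015514 open calls and replicate 2 holds 4343 barcodes with 33360269 open calls. A region with 3 or fewer open calls in a class lies at the floor used below. Intervals and floors cover counting error only.

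Barcodes with fewer than 1000 open regions were removed (7 in replicate 1 and 12 in replicate 2). Doublets were predicted in each library from simulated sums of barcode pairs, and the highest-scoring barcodes were removed at 0.8% per 1000 barcodes (214 in replicate 1 and 150 in replicate 2). The 9141 remaining cells were embedded by latent semantic indexing (term frequency-inverse document frequency and singular value decomposition, 30 components, 1 dropped for a correlation of 0.7 or more in size with depth). Regions open in fewer than 50 cells were left out of this step. Cells were clustered with Leiden (leidenalg 0.10.2, igraph 0.11.9) at a resolution of 0.5 on a shared-neighbour graph with 20 neighbours, which gave 15 clusters. These steps ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0.

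Clusters were named by marker genes fixed before the data were examined. A cluster took the class whose markers had the highest mean log2 ratio to the other clusters, if at least 3 of them were raised by 1 or more on the log2 scale and the next class was at least 0.25 lower. It stayed unnamed where its 10 most raised genes held more markers of another class. The margin of 0.25 was set after the data were seen. Marker genes named the classes, so their own differences between classes are not independent evidence.

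A gene's value was the sum of open calls in regions that overlap its span, extended by 2 kb at both ends, for protein coding genes of the RefSeq annotation of the mm10 assembly. The annotation at hand has no strand. The planned 2 kb upstream of the start could therefore not be told from the other end, and both ends were used. Of 21887 protein coding genes, 17217 had a region, and 62.2% of regions fell in or near a gene. A region can count for more than 1 gene (3.4% of regions did), and genes whose calls came largely from a neighbour are named as such. Accessibility of a gene is not its expression.

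Open calls were summed per library and class, which gave 8 sums for the 4 classes with at least 50 cells in each library. To keep the cells' class labels apart from the data tested, odd-numbered chromosomes were tested in classes clustered on even-numbered chromosomes, X and Y, and the reverse. The 2 sets of labels put 99.3% of cells in the same class. Each class was compared with the mean of the other 3 classes on the log scale with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test, with TMM factors, the low-count filter of edgeR and the library as a block, which left 3 residual degrees of freedom. Genes and regions were called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 fold change of at least 1 in size. Because the contrast averages logarithms, a gene that is very low in 1 class can pass although another class lies above it, so a gene called higher in a class need not be highest there. Levels are CPM, open calls scaled to a common library total with TMM factors, as mean and SD over 2 libraries. The common biological coefficient of variation was 2.21% for genes and 4.51% for regions.

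Named genes followed a rule fixed before the data were examined. For each class they were the 8 called genes with the largest log2 fold change up and the 4 with the largest down. They had to go the same way in both libraries, reach 20 CPM on the higher side, share at most 50% of their calls with another gene and not be a marker. In addition, up to 2 called members of each gene list with the largest change were named, or the member with the highest CPM where none was called, and the 3 regions with the largest rise. Where a gene had 3 or fewer counts in some class, the fitted fold change depends on the prior count, and the ratio of CPM to the mean of the other classes is given instead. With 1 to 3 counts in the lower group that ratio carries a 95% counting interval, and with 0 counts it is a lower bound against a floor of 3 counts over the group's libraries.

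The 21 gene lists were fixed from textbook knowledge before the data were examined and were tested in each class with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 84 tests. Markers used for naming were left out. The test was repeated with an estimated correlation, under which the smallest adjusted p of the 84 tests was 0.395. This repeat rests on the 3 residual degrees of freedom, so p can rise even where the estimated correlation is below 0.01. For VEGF and angiopoietin genes in endothelial cells that correlation was -0.025, and the unadjusted p of camera rose from 5.66e-04 to 0.0355. The repeat therefore cannot tell correlation between genes from the few degrees of freedom. Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals and were set side by side without a test, since the labels hold only 1 group.

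The same test was checked on simulated counts with the real library sizes, a fixed dispersion and the mean of each gene or region pooled over the classes. Simulated 8-fold rises of genes were called in 100% of cases in each class, and 3-fold rises in 96% (mural) to 100%. Lowered genes were called in 84% to 100% of cases. Lowered regions were called far less often, in 14% (mural) to 54% at 3-fold and in 24% (mural) to 76% at 8-fold, and raised regions in 32% (mural) to 92% at 3-fold and 86% (mural) to 100% at 8-fold, so counts of lower regions, and of higher regions in mural cells above all, are incomplete. Unchanged genes and regions were called in at most 0.006% of cases. Apart from the changed genes and regions the simulated classes were alike. The real classes differ widely, so this rate does not show how many calls are false in these data. The check was first set to require over 80% at 8-fold for all fibroblast cases and failed on lowered regions. It was then limited to raised genes.

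Alternatives were RLE normalization, DESeq2 1.42.0, no library block, no low-count filter and labels from 1 clustering. Further ones were Leiden resolutions of 0.3 and 1.0, doublets kept, a minimum of 3000 open regions and centring per library. Others were chosen after the data were seen: cells of matched depth (4000 to 7000 open regions), the unnamed myeloid cluster added to macrophages, open calls without TMM factors, regions within 1 kb of gene ends, gene spans without extension, and the same settings for subset comparisons. No reference genome was at hand, so the planned motif shares were not run, and without strand the planned promoter values were not run. The planned use of cells with a region open moves nothing in capped values, and the planned overlap of region lists does not apply to 1 shared list.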

Results

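Single-cell accessibility of chromatin was measured in sorted live non-myocytes of the adult mouse heart. The stated purpose was to profile the epigenome of these cells, and the labels hold no second condition. The data comprised 2 libraries of 1 group. Replicate 1 held 5181 barcodes with 41015514 open calls and a median of 7709 open regions per barcode. Replicate 2 held 4343 barcodes with 33360269 open calls and a median of 7614. The comparisons below ask which cell classes the libraries held, in what shares, and which genes and regions were more or less accessible in each class than in the others.

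After removal of 19 shallow barcodes and 364 predicted doublets, 9141 cells remained, 4960 in replicate 1 and 4181 in replicate 2. Fibroblasts were the largest class, with 47.1% of cells in replicate 1 (95% interval 45.7% to 48.5%) and 58.5% in replicate 2 (57.0% to 59.98%). Endothelial cells made up 27.2% (26.0% to 28.5%) and 19.9% (18.7% to 21.1%). Macrophages and monocytes made up 16.9% (15.9% to 18.0%) and 16.3% (15.2% to 17.4%). Mural cells, the pericytes and smooth muscle cells around vessels, made up 4.25% (3.71% to 4.85%) and 2.27% (1.84% to 2.77%). Granulocytes made up 1.63% (1.30% to 2.03%) and 1.03% (0.745% to 1.38%), and B cells 0.645% (0.442% to 0.91%) and 0.359% (0.201% to 0.591%). Cells of 2 clusters without a clear name made up 2.20% (1.81% to 2.65%) and 1.72% (1.35% to 2.16%). As means over libraries the shares were 52.8% ± 8.02 (SD, n = 2) for fibroblasts, 23.5% ± 5.19 for endothelial cells, 16.6% ± 0.458 for macrophages and monocytes and 3.26% ± 1.40 for mural cells. The intervals of the fibroblast, endothelial and mural shares did not overlap between the libraries, and those of macrophages did. Depth differed between classes. The median number of open regions per cell was 8956 in fibroblasts, 7822 in macrophages and monocytes, 5995.5 in mural cells and 4750 in endothelial cells. Leiden resolution 1.0 left more cells unnamed (7.58% of cells as a mean over libraries) and lowered the endothelial share to 17.9%.

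**Figure D1:**
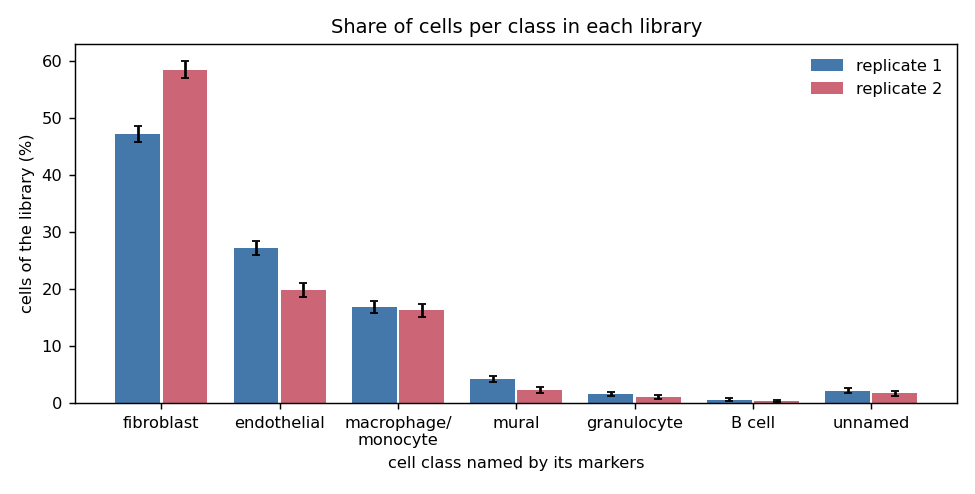
Percent of cells per class in each of the 2 libraries, with exact 95% binomial intervals as error bars. Fibroblasts were the largest class in both libraries (47.1% and 58.5%), followed by endothelial cells (27.2% and 19.9%).

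The markers that named the classes differed as follows. In fibroblasts Dpt, a matrix protein gene, had 147 ± 4.25 CPM (SD, n = 2) against a mean of 7.97 in the other classes, and Ddr2, a collagen receptor gene, had 345 ± 20.7 against 46.0. In endothelial cells Erg, an ETS factor, had 303 ± 21.0 against 18.1, and Flt1, a VEGF receptor, had 455 ± 24.9 against 38.01. In macrophages and monocytes Csf1r, the receptor of macrophage colony-stimulating factor, had 178 ± 0.101 against 7.49. In mural cells Rgs5 had 113 ± 7.33 against 7.97 and Pdgfrb had 311 ± 34.1 against 75.3. Cnn1, a smooth muscle marker, had only 3.02 ± 0.736 in mural cells against 1.90 (log2 fold change 0.76 ± 0.78 SE). Markers fixed for other cell types also differed. In macrophages and monocytes the dendritic marker Ciita, the activator of MHC class II genes, had 124 CPM against 15.2, and the granulocyte marker Mmp9 had 74.1 against 17.03. In fibroblasts Pdpn, fixed as a lymphatic endothelial marker, had 206 against 29.7.

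**Figure D2:**
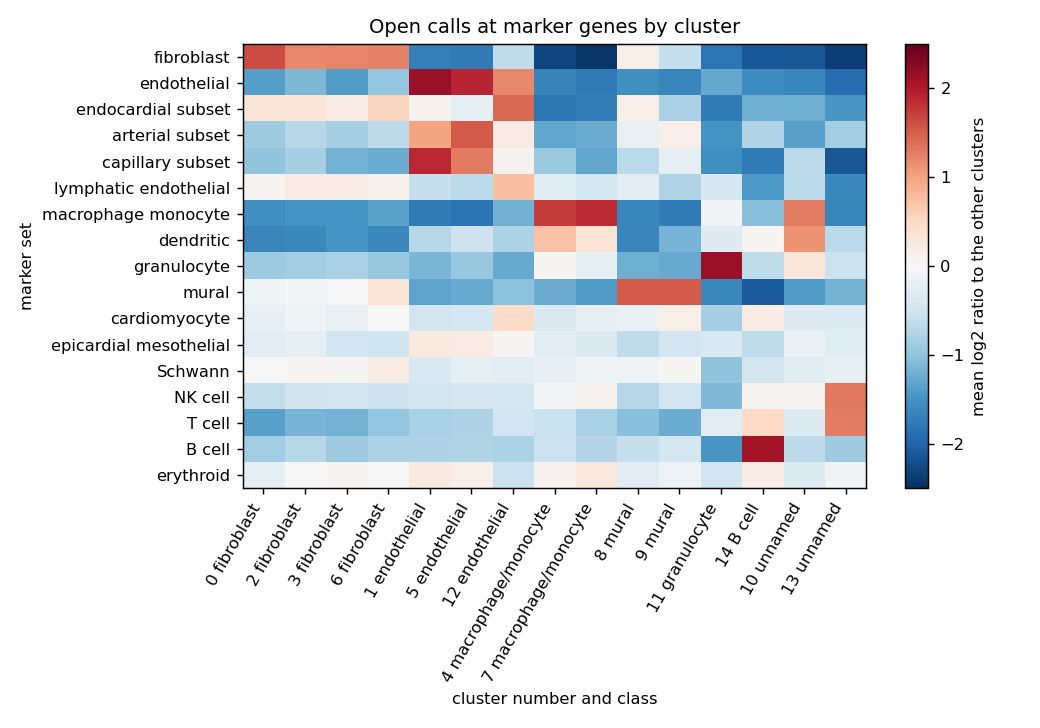
Mean log2 ratio of the open calls at marker genes to the other clusters (colour, red higher and blue lower), for each fixed marker set (vertical axis) in each of the 15 clusters with its number and class (horizontal axis). Fibroblast markers stand at 1.64 in fibroblast cluster 0 and endothelial markers at 2.15 in endothelial cluster 1.

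Fibroblasts were compared with the mean of the other 3 classes. The genes with the largest rise included matrix and secreted-protein genes and, beside them, genes of striated muscle. Myom2, which codes for a protein of the muscle sarcomere (chromosome 8, 15057653 to 15133420), had 37.8 ± 2.28 CPM (SD, n = 2) against 0.676, a ratio of 55.9. Trdn, which codes for triadin of the muscle calcium release complex, had 36.2 ± 4.75 against 0.849. Efemp1, a fibulin gene, had 37.6 ± 0.64 against 1.52, and Serpina3n, a secreted protease inhibitor gene, had 75.6 ± 7.37 against 1.88. Serpina6, which codes for corticosteroid-binding globulin, had 21.8 ± 4.92 against 0.591. Serpinb9b (20.2 against 0.56), Cga (33.4 against 0.982) and Cyp2c23 (21.9 against 3.76) completed the 8. The largest falls were in St8sia4, a polysialyltransferase gene (log2 fold change -5.48 ± 0.22 SE), Ednrb, an endothelin receptor (-4.46 ± 0.11), and Gimap6, a gene of the GTPases of immune-associated proteins (-4.10 ± 0.19). Ctla2b had 0.44 CPM against 36.0. In all, 3013 of 16749 genes were higher and 568 lower (edgeR quasi-likelihood, adjusted p under the threshold, both libraries alike in 3012 and 568). Of the raised genes, 1102 were also higher than in each other class tested singly. Beside the muscle genes, the 7 tested markers of cardiomyocytes had a median log2 fold change of 0.04 in replicate 1 and 0.20 in replicate 2, with Ryr2, the calcium release channel, at 2.29 ± 0.20. For the 5 of these that share fewer of their calls with a neighbour the median was 0.648 and 0.475.

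Matrix lists were raised in fibroblasts. Of 23 extracellular matrix glycoproteins and modifiers, 18 were higher and 0 lower (camera, adjusted p = 4.2e-10), among them Loxl1, a collagen and elastin crosslinking enzyme (log2 fold change 4.46 ± 0.07 SE), and Fbln1 (4.38 ± 0.07). With an estimated correlation the adjusted p of this list, and of each other list called higher in fibroblasts, was 0.395. Of 13 collagens, 11 were higher (1.65e-08), led by Col6a3 (4.19 ± 0.08) and Col6a1 (4.18 ± 0.19). Of 18 Wnt pathway genes 10 were higher (5.67e-06), including the secreted Wnt antagonist Sfrp1 (3.93 ± 0.11) and the ligand Wnt5a (3.29 ± 0.10). Of 21 TGF-beta and BMP genes 8 were higher (1.75e-03), including Ltbp1, which binds latent TGF-beta (2.63 ± 0.05), and Bmp6 (2.52 ± 0.07). Of 17 cardiac developmental transcription factors 8 were higher (1.08e-03), with Tbx20 at 2.88 ± 0.07 and Tbx5 at 2.71 ± 0.11. Both were as accessible in mural cells, at 93.1 CPM for Tbx20 and 52.8 for Tbx5, against 95.3 and 49.7 in fibroblasts. Of 19 smooth muscle genes 10 were higher (1.49e-04). Several of these had a higher level still in mural cells, as Gucy1a1, a subunit of the nitric oxide receptor, did with 43.8 CPM in fibroblasts, 88.0 in mural cells and 0.87 in macrophages. Kcnma1, a potassium channel gene, was highest in fibroblasts (178 CPM against 62.3 in mural cells).

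Of the lists lower in fibroblasts, 3 passed. With an estimated correlation their adjusted p was 0.395 for complement and receptor genes, 0.436 for endothelial factors and 0.395 for cell cycle genes. Of 14 complement, scavenger and Fc receptor genes, 10 were lower (camera, adjusted p = 0.0128), such as C1qc (log2 fold change -3.32 ± 0.61 SE), and Msr1, a scavenger receptor, had 1.11 CPM against 42.2. Of 16 endothelial transcription factors 5 were lower and 2 higher (0.0281), with Hhex at -2.54 ± 0.19 and Sox18 at 1.32 CPM against 16.2. Of 13 cell cycle genes 0 passed in either direction (0.0293 for the list, downward), with Pcna, most of whose calls are shared with Cds2, at -0.21 ± 0.05. Adjusted over the list alone, the counts of all 21 lists were the same in this class. The other 12 lists did not pass. Their counts were 5 higher and 2 lower of 12 for platelet-derived and fibroblast growth factors (adjusted p = 0.309), where Fgf10 had 9.23 CPM against 0.552 and Pdgfb had a log2 fold change of -3.87 ± 0.10. They were 5 and 1 of 13 for VEGF and angiopoietins (0.196), with Angpt1 at 3.76 ± 0.09. They were 1 and 3 of 14 for Notch (0.196), 5 and 0 of 14 for sarcomere and conduction (0.117), and 0 and 1 of 14 for myeloid factors (0.983). Casq2, of the sarcomere list, had 39.0 CPM in fibroblasts and 107 in mural cells. Counts were 1 and 2 of 14 for Toll-like receptors (0.203), 0 and 2 of 9 for MHC class II (0.112), and 4 and 1 of 17 for chemokines (0.701). They were 1 and 0 of 12 for lipid handling (0.888), 3 and 2 of 19 for HOX genes (0.457), 0 and 0 of 15 for AP-1 genes (0.0703) and 0 and 0 of 14 for housekeeping genes (0.0709). DESeq2 also called 0 in the cell cycle, AP-1 and housekeeping lists, where 11, 8 and 9 genes had an unadjusted p under 0.05 at any fold (edgeR). For chemokines the median (-0.25) differed in sign from the mean (0.11) and the test (up). For lipid handling the median (0.21) and mean (0.15) were positive and the test pointed down. For myeloid factors the median (0.08) was positive and the mean (-0.04) and test were not.

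Of 125822 regions, 45353 were higher in fibroblasts and 15810 lower (edgeR quasi-likelihood). The region with the largest rise (chromosome 7, 72441875 to 72442827) had 23.1 ± 3.64 CPM (SD, n = 2) against 0.171, and lay 134759 bp from its nearest gene, Mctp2. The next lay within Sgcd, a sarcoglycan gene (chromosome 11, 47705025 to 47706526), with 27.8 ± 1.94 against 0.284, and within Myom2 (chromosome 8, 15071615 to 15073485), with 24.5 ± 2.25 against 0.506. With cells of matched depth, 19994 regions were higher and 3858 lower, among 62167 tested, and DESeq2 called 27420 lower. Without TMM factors the median over genes moved from 0.032 to -0.091 on the log2 scale, so fibroblast changes are relative to that choice. For regions the same step moved the median from 0.251 to 0.419 in fibroblasts, from 0.125 to -0.106 in endothelial cells, from 0.118 to -0.245 in macrophages and monocytes and from -0.556 to -0.085 in mural cells.

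Endothelial cells were compared in the same way. Of their list members, endothelial transcription factors stood out. Of 16, 10 were higher and 0 lower (camera, adjusted p = 2.96e-07), with Sox18 at 44.8 ± 2.46 CPM (SD, n = 2) against 1.74, and Gata2 at a log2 fold change of 3.49 ± 0.07 SE. With an estimated correlation the adjusted p of this list and of the other 6 that passed lay between 0.395 and 0.414. Of 13 VEGF and angiopoietin genes 4 were higher and 2 lower (2.07e-03), with Ptprb, a vascular phosphatase, at 3.22 ± 0.07 and the apelin receptor Aplnr at 29.1 CPM against 5.26. Of 19 HOX genes 6 were higher and 1 lower (0.0293), such as Hoxa2 at 16.5 CPM against 5.99. Several HOX genes share their regions with a neighbour, so their number is uncertain. Smooth muscle genes were lower in 14 of 19 (8.62e-03), with the endothelin receptor Ednra at -2.92 ± 0.39 (2.69 CPM, and 1.20 in macrophages). Myeloid factors were lower in 4 of 14 (0.0128), with Irf5 at -2.64 ± 0.14 and Tfec at -2.86 ± 0.50. MHC class II genes were lower in 7 of 9 (0.025), with the invariant chain Cd74 at -2.68 ± 0.23. The 14 housekeeping genes leaned upward (0.0128, median 0.21), with 0 called and Actb at 0.41 ± 0.05. Adjusted over the list alone, the counts of all 21 lists were the same in this class.

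The named genes with the largest rise in endothelial cells were mostly ones with no known vascular role, and some rest on a single region. Aym1 (chromosome 5, 113357294 to 113357821, 1 region) had 22.3 ± 0.37 CPM (SD, n = 2) against 0.173, a ratio of 129. The predicted genes Gm3667 (21.5 against 0.341) and Gm10406 (20.3 against 0.8) lie near each other on chromosome 14. The olfactory receptor genes Olfr56 (22.9 against 0.234), Olfr687 (45.2 against 0.929) and Olfr1396 (21.2 against 0.287), the zinc finger gene Zfp985 (28.1 against 0.575) and Stmn2 (41.1 ± 2.37 against 0.593), a microtubule regulator of neurons, completed the 8. Falls were largest in the chemokine Ccl9 (log2 fold change -4.97 ± 0.41 SE), Ocstamp (-4.72 ± 0.29), the integrin Itga4 (-4.65 ± 0.25) and Vstm4 (-4.31 ± 0.12). In all, 1088 of 16749 genes were higher and 2226 lower (edgeR quasi-likelihood), and 348 were higher than in each other class. Both libraries went the same way in 1088 and 2215. The median endothelial cell had the fewest open regions of the 4 classes (4750).

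Among endothelial lists that did not pass, single members differed strongly. Counts were 4 higher and 2 lower of 14 for Notch (adjusted p = 0.0663), with the ligand Jag2 at a log2 fold change of 3.70 ± 0.07 SE. They were 2 and 3 of 12 for platelet-derived and fibroblast growth factors (0.815), with Pdgfd at 4.22 ± 0.10. They were 3 and 2 of 12 for lipid handling (0.0807), with Tcf15, a factor of heart capillary endothelium, at 2.75 ± 0.08. They were 0 and 7 of 13 for collagens (0.161), with Col14a1 at -2.52 ± 0.12, and 3 and 9 of 23 for matrix glycoproteins (0.127), with Postn at -3.36 ± 0.20. They were 4 and 3 of 21 for TGF-beta and BMP (0.327), with Bmp2 at -3.34 ± 0.14. They were 3 and 5 of 17 for cardiac factors (0.49), with Tbx20 at -3.72 ± 0.17, and 2 and 6 of 18 for Wnt (0.391), with Sfrp2 at -3.25 ± 0.36. They were 0 and 4 of 14 for Toll-like receptors (0.117), 1 and 5 of 14 for complement and Fc receptors (0.457), and 2 and 7 of 17 for chemokines (0.161). They were 3 and 1 of 14 for sarcomere and conduction (0.833), with the gap junction gene Gja1 at 2.46 ± 0.12. Cell cycle (0.683) and AP-1 genes (0.0783) had 0 called. In these and the housekeeping list DESeq2 also called 0, and 4, 12 and 10 genes had an unadjusted p under 0.05 at any fold (edgeR).

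Of 125822 regions, 24457 were higher in endothelial cells and 15920 lower (edgeR quasi-likelihood). The largest rise, within Ccdc85a (chromosome 11, 28465575 to 28466539), was 24.7 ± 0.68 CPM (SD, n = 2) against 0.007, which is 1 open call in the other classes (ratio 3500, 95% counting interval 629 to 138000). Another large rise lay 288916 bp from Igfbp3 (chromosome 11, 7504414 to 7505394), at 43.5 ± 3.53 against 0.11. With cells of matched depth 13011 regions were higher and 6488 lower.

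Macrophages and monocytes were compared in the same way. C5ar1, the receptor of complement C5a (chromosome 7, 16246743 to 16259540), had 154 ± 0.46 CPM (SD, n = 2) against 1.05, a ratio of 147. Ms4a7 had 78.8 ± 0.83 against 0.46, a ratio of 172. The lectin receptors Clec4n (51.4 against 0.379) and Clec4a3 (37.7 against 0.283), the sialic acid receptor Cd33 (76.5 against 0.587) and the immune cell receptors Slamf7 (83.5 against 0.724) and Cd84 (71.6 against 0.571) were among the 8, with the olfactory receptor gene Olfr111 (43.3 against 0.343). These 8 genes had 0 counts in mural cells. Falls were largest in the potassium channel Kcna5 (log2 fold change -6.38 ± 0.29 SE), the glypican Gpc4 (-6.28 ± 0.24) and Tm4sf1 (-6.02 ± 0.16). Gm536 fell to 0.3 CPM against 22.0 (ratio 73.4, 95% counting interval 25.1 to 356). In all, 2072 of 16749 genes were higher and 2439 lower (edgeR quasi-likelihood), and 1139 were higher than in each other class. Both libraries went the same way in 2072 and 2437.

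Immune lists were raised in macrophages and monocytes. Of 14 Toll-like receptors and innate sensing genes 13 were higher (camera, adjusted p = 5.85e-07), with Tlr13 at 21.9 CPM against 0.284 and the fungal sensor Clec7a at 38.3 against 0.42. With an estimated correlation the adjusted p of this list, and of each other list that passed in this class, was 0.395. Of 14 complement, scavenger and Fc receptor genes 12 were higher (5.85e-07), with C3ar1 at 89.8 against 0.718. Of 9 MHC class II presentation genes 8 were higher (5.4e-05), with the costimulator Cd86 at 274 against 3.10. Of 17 chemokines and receptors 13 were higher and 2 lower (1.39e-04), with Ccl24 at 57.4 against 0.426 and Ccr1 at 31.8 against 0.297. Of 14 myeloid transcription factors 6 were higher (1.15e-03), with Ikzf1 at a log2 fold change of 5.41 ± 0.13 SE and Tfec at 4.08 ± 0.17. Dendritic and granulocyte markers were raised beside these lists, as given above for Ciita and Mmp9.

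Structural and developmental lists lay lower in macrophages and monocytes. They fell in 13 of 19 smooth muscle genes (camera, adjusted p = 4.25e-07), 15 of 23 matrix glycoproteins (1.03e-06), 11 of 13 collagens (1 higher, 2.83e-04), 10 of 18 Wnt genes (2.59e-04) and 10 of 17 cardiac factors (5.73e-04). With an estimated correlation each had an adjusted p of 0.395. They also fell in 6 of 13 VEGF and angiopoietin genes (1 higher, 6.93e-03) and 9 of 21 TGF-beta and BMP genes (1 higher, 0.0226). Col6a2 had a log2 fold change of -5.06 ± 0.29 SE, Thbs2 of -5.02 ± 0.24, Gucy1a1 of -4.93 ± 0.29, Wnt5a of -4.46 ± 0.26, Bmp4 of -4.85 ± 0.22 and Tbx18 of -4.08 ± 0.16. Adjusted over the list alone, the counts of all 21 lists were the same in this class. Lists that did not pass held strong single members. Counts were 2 higher and 6 lower of 12 for platelet-derived and fibroblast growth factors (0.117), with Pdgfc at 4.997 ± 0.11 and Pdgfd at -4.26 ± 0.29. They were 4 and 4 of 16 for endothelial factors (0.51), where the median (0.17) and the test were positive and the mean (-0.27) was not, with Nr2f2 at -4.88 ± 0.13. They were 2 and 2 of 14 for Notch (0.81), with Heyl at -5.15 ± 0.15. They were 2 and 5 of 12 for lipid handling (0.181), with Tcf15 at -4.45 ± 0.16. They were 0 and 5 of 14 for sarcomere and conduction (0.161), with Casq2 at -5.55 ± 0.26, and 6 and 3 of 19 for HOX genes (0.31). Housekeeping (0.768), cell cycle (0.457) and AP-1 genes (0.303) had 0 called by edgeR and by DESeq2. Their genes with an unadjusted p under 0.05 at any fold numbered 8, 5 and 10.

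Of 125822 regions, 39014 were higher in macrophages and monocytes and 31406 lower (edgeR quasi-likelihood). Without TMM factors 34867 were higher and 37246 lower, and with cells of matched depth 14950 were higher and 15298 lower, so which side was larger depended on these settings, of which matched depth also had fewer cells and regions (62167). The largest rise (chromosome 14, 47361634 to 47362514), 11346 bp from Lgals3, a galectin gene of macrophages, was 64.8 ± 0.17 CPM (SD, n = 2) against 0.095, a ratio of 680. The next lay 76716 bp from Wwox (chromosome 8, 115429428 to 115430075), at 31.4 ± 2.24 against 0.014, and 31925 bp from Trappc8 (chromosome 18, 20784846 to 20785286), at 31.2 ± 2.70 against 0.022.

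Mural cells had the fewest cells of the 4 tested classes (306) and the widest spread between libraries. Their genes of largest rise included ion channel and signalling genes of vascular smooth muscle. Trpc6, a cation channel (chromosome 9, 8543867 to 8680752, 1 region), had 40.6 ± 10.2 CPM (SD, n = 2) against 0.368, a ratio of 110. Rgs4, a regulator of G protein signalling, had 41.4 ± 10.99 against 1.52. Lin7a had a log2 fold change of 5.42 ± 0.21 SE, Bmp5 of 5.47 ± 0.31 and Amph of 5.21 ± 0.33. Pex5l (44.0 against 1.15), Nell1 (20.1 against 0.824) and the olfactory receptor gene Olfr71 (26.8 against 0.423) completed the 8. The 4 genes with the largest falls had 0 counts in mural cells. Il21r, an interleukin receptor gene, was at least 26.9-fold lower than the other classes, Serpinb8 at least 13-fold, Ptgs2, which codes for cyclooxygenase-2, at least 12.8-fold and Ms4a6d at least 12.4-fold. In all, 1301 of 16749 genes were higher and 1162 lower (edgeR quasi-likelihood), and 279 were higher than in each other class. Both libraries went the same way in 1291 and 1161. With regions at gene ends alone 583 genes were lower.

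Contractile genes were raised as a list in mural cells. Of 19 smooth muscle genes 14 were higher and 0 lower (camera, adjusted p = 5.74e-18), with the intermediate filament gene Des at a log2 fold change of 4.64 ± 0.22 SE. With an estimated correlation the adjusted p of this list and of the other 6 that passed was 0.395. Of 23 matrix glycoproteins 10 were higher and 1 lower (3.03e-06), with the crosslinking enzyme Loxl2 at 3.00 ± 0.25 (42.2 CPM, and 50.1 in fibroblasts). Of 17 cardiac transcription factors 6 were higher (1.15e-03), with Tbx18 at 3.05 ± 0.14. Of 13 collagens 6 were higher and 1 lower (6.93e-03), with Col6a2 at 3.03 ± 0.24, at 48.3 CPM in mural cells and 52.1 in fibroblasts. Lower lists were endothelial factors, with 6 of 16 lower and 1 higher (1.48e-03), as Lyl1, most of whose calls are shared with Trmt1, at -2.13 ± 0.23, and Toll-like receptors with 5 of 14 lower (1.48e-03), as Nlrp3 at 0.42 CPM against 48.2. MHC class II genes were lower in 2 of 9 (0.0293), as H2-Aa at -2.06 ± 0.43. Adjusted over the list alone, endothelial factors had 7 lower, and the other 6 lists had the same counts.

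Mural lists that did not pass had these counts. They were 3 higher and 0 lower of 18 for Wnt (adjusted p = 0.0653), with Wnt5a at a log2 fold change of 2.76 ± 0.23 SE (49.1 CPM, and 69.2 in fibroblasts), and 2 and 3 of 14 for Notch (0.51), with Heyl, a Notch target, at 3.58 ± 0.11. They were 4 and 4 of 14 for sarcomere and conduction (0.457), with Casq2, the calsequestrin of the calcium store, at 4.03 ± 0.19. They were 1 and 3 of 13 for VEGF and angiopoietins (0.575), with Angpt2 at 2.26 ± 0.16, whose regions lie within another gene. They were 2 and 0 of 21 for TGF-beta and BMP (0.246), with Bmpr1a at 1.19 ± 0.12, and 2 and 1 of 12 for growth factors (0.264), with Fgf1, which shares its regions, at 1.87 ± 0.10. They were 3 and 2 of 12 for lipid handling (0.0851), 1 and 5 of 19 for HOX genes (0.0851), 0 and 3 of 14 for myeloid factors (0.293) and 1 and 6 of 17 for chemokines (0.241). They were 0 and 5 of 14 for complement and Fc receptors (0.0844), and 7 lower when adjusted over the list alone. Housekeeping (0.457), cell cycle (0.941) and AP-1 genes (0.51) had 0 called by edgeR and by DESeq2, and 3, 0 and 4 of their genes had an unadjusted p under 0.05 at any fold. Over the list alone 5 sarcomere genes and 2 growth factor genes were lower, and the other lists had the same counts. The median and the test of the growth factor, sarcomere and Notch lists were positive and their means negative, and the housekeeping median (0.01) was positive where the mean and test were negative.

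Of 125822 regions, 15161 were higher in mural cells and 11243 lower (edgeR quasi-likelihood). The largest rise (chromosome 7, 70847455 to 70847988), 262494 bp from Gm44812, was 20.1 ± 6.31 CPM (SD, n = 2) against 0.126. The next lay 3583 bp from Rgs4 (chromosome 1, 169737306 to 169737894), at 35.4 ± 6.17 against 0.437, and within Daam2 (chromosome 17, 49519900 to 49520444), at 30.8 ± 9.47 against 0.307. With cells of matched depth 8987 regions were higher and 2258 lower, and 4854 were lower without TMM factors and 4870 with DESeq2.

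**Figure D3:**
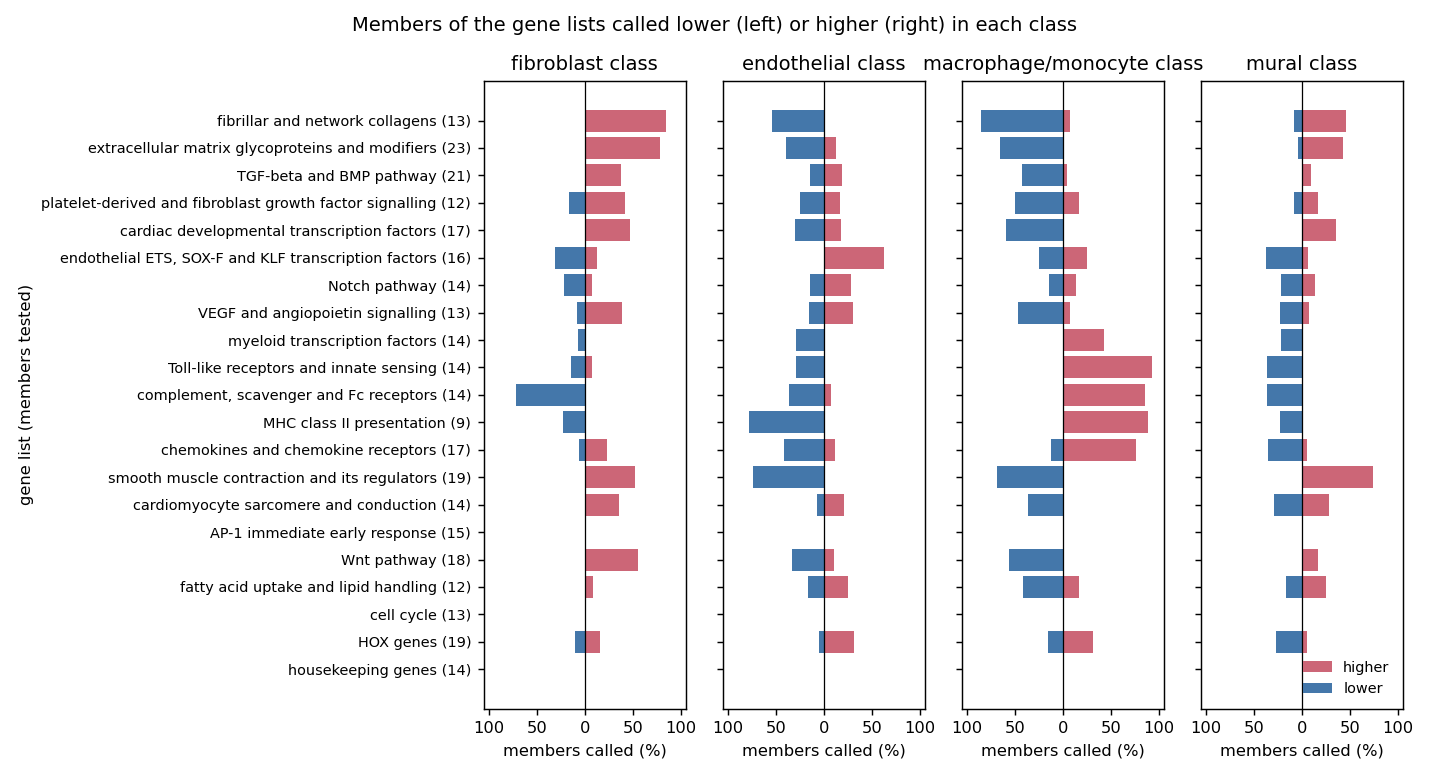
Percent of the tested members of each gene list (vertical axis, number tested in brackets) called higher (bars to the right) or lower (bars to the left) in each of the 4 classes (panels). Smooth muscle genes were higher in 14 of 19 in mural cells and lower in 13 of 19 in macrophages and monocytes.

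Within endothelial cells, clusters with arterial and capillary markers were compared. Only odd-numbered chromosomes could be tested, since clustering on these did not separate the subset markers. Of 7952 genes, 56 were higher in the arterial cluster and 74 lower (edgeR quasi-likelihood). Raised genes included Prom1, a membrane protein of stem and endothelial cells at 69.0 ± 5.30 CPM (SD, n = 2) against 19.2 and a log2 fold change of 1.81 ± 0.24 SE, Crispld1 (1.94 ± 0.23), Plekhs1 (1.99 ± 0.27), Pcolce2 (2.12 ± 0.39) and Neu2 (2.65 ± 0.47). Sgpp2 (1.95 ± 0.33), Pdcl2 (1.90 ± 0.28) and Clca3a1 (1.74 ± 0.45) completed the 8. Falls were largest in the NADPH oxidase Nox4 (-2.92 ± 0.48), Slamf9 (-2.19 ± 0.48), Fmo6 (-2.13 ± 0.28) and the potassium channel Kcnk2 (-2.11 ± 0.31). Of 3 arterial markers on the tested chromosomes 1 was higher, Gja5, a gap junction gene of arteries, and of 4 capillary markers 0 were called by edgeR or DESeq2, with 2 at an unadjusted p under 0.05 at any fold. Arterial and capillary markers, Gja5 among them, named these clusters, so their differences are not independent evidence. Of 3 cardiomyocyte markers 1 was higher, Tnnt2 (median 0.34), and of 4 endocardial markers 0 were called, with 1 lower at an adjusted p under 0.05 at any fold (median -0.53). DESeq2 called 10 higher and 18 lower, and the fit without library block called 47 lower, so these counts depend on the test.

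The libraries were close to each other within classes. Across genes, which are not independent replicates, the Pearson correlation of log2 levels between libraries was 0.997 in fibroblasts, 0.990 in endothelial cells, 0.994 in macrophages and monocytes and 0.958 in mural cells (Spearman 0.998, 0.993, 0.995 and 0.971). Across regions it was 0.992, 0.969, 0.980 and 0.885 (Spearman 0.987, 0.902, 0.951 and 0.7997). Regions at the distal ends of X and Y were an exception. In fibroblasts the 12 distal regions of Y had 92.4 CPM without TMM factors in replicate 1 and 25.7 in replicate 2, a ratio of 3.59, and the ratio was 2.64 in endothelial cells, 3.70 in macrophages and monocytes and 3.28 in mural cells. For the 11 distal regions of X the ratios were 1.93, 1.46, 2.08 and 1.43. For the other 15 regions of Y they were 1.096, 1.06, 1.01 and 0.696, and for autosomes they lay between 0.999 and 1. The distal sets hold 8 of the 10 regions that ranked highest by this ratio in the 3 large classes, which raises their values. Without those 8 the log2 ratios of distal Y were 1.565, 0.591, 1.931 and 1.423. For distal X they were 0.156 (0.007 to 0.304), 0.206 (-0.027 to 0.439), 0.527 (0.324 to 0.729) and -0.249 (-1.13 to 0.631), in the same order of classes.

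**Figure D4:**
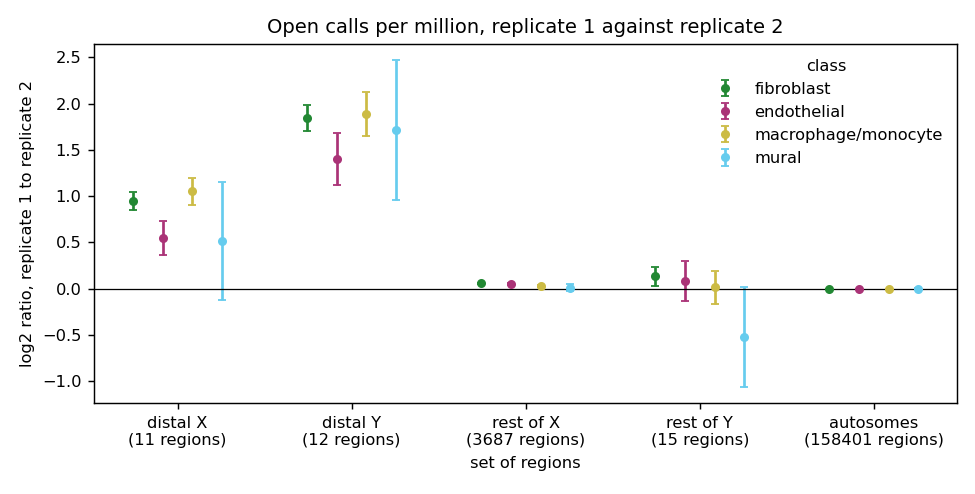
Log2 ratio of CPM in replicate 1 to replicate 2 (vertical axis) for sets of regions on X, Y and autosomes (horizontal axis), with a point per class and a 95% interval for counting error. In fibroblasts the distal regions of Y stand at 1.85 and the rest of Y at 0.13. The distal sets include 8 regions that ranked among the highest by this same ratio. Without these, distal Y had 1.565 and distal X 0.156 in fibroblasts.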

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

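Cells of 5 small clusters entered no comparison of their own in the report. Their shares were given without a test, so no test among them was chosen after the result was seen. No technical or biological explanation was tested for them.

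A cluster with granulocyte markers (mean log2 ratio to the other clusters 2.14), with S100a9 and Trem1 among its most raised genes, made up 1.63% of replicate 1 and 1.03% of replicate 2. A cluster with B cell markers (2.09) made up 0.645% (32 cells) and 0.359% (15 cells). A cluster with markers of both macrophages (1.27) and dendritic cells (1.13), with the coagulation factor genes F7 and F10 among its most raised genes, made up 1.31% (1.01% to 1.67%) and 1.48% (1.14% to 1.90%). A cluster with markers of both NK cells (1.33) and T cells (1.28), with the perforin gene Prf1 among its most raised genes, made up 0.887% (0.645% to 1.19%) and 0.239% (0.115% to 0.439%). A cluster of the endothelial class with markers of the endocardium (1.43), the inner lining of the heart, had Wnt2 among its most raised genes. It made up 0.927% (0.68% to 1.24%) of replicate 1 and 0.239% (0.115% to 0.439%) of replicate 2, and entered the endothelial class but not the comparison of arterial with capillary cells.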

How the results depend on the processing

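The alternatives with cells of matched depth, the unnamed myeloid cluster added to macrophages, no TMM factors, gene ends, gene spans without extension and those of the arterial subset were chosen after the result was seen. Of 207 counts and shares under alternatives with both libraries, 192 stayed within 1.5 times the reported count or within the spread of the share, and 15 did not. The 42 values from 1 library alone say nothing about stability, since with 2 libraries a share always lies within their spread, and the counts are of genes already called with both libraries whose log2 fold change in the remaining one was at least 1 in size. These counts ranged from 2727 to 2830 for genes higher in fibroblasts, 980 to 997 in endothelial cells, 1901 to 1967 in macrophages and monocytes and 1102 to 1216 in mural cells. For 198 pairs of a named gene and class, 3138 alternative values held 6 reversals, 45 losses of an adjusted p under 0.05 and 5 gains. Values of these pairs from 1 library alone moved by more than the spread in 142 of 198 without replicate 1 and in 88 without replicate 2. Of the losses 17 came with cells of matched depth and 18 with regions at gene ends.

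With cells of matched depth, regions higher numbered 19994 in fibroblasts, 13011 in endothelial cells, 14950 in macrophages and monocytes and 8987 in mural cells, among 62167 regions tested against 125822, so fewer regions were tested. That setting reversed Tyrobp in endothelial cells (log2 fold change 0.285, from -2.22), Zfp36 in endothelial (-0.064) and mural cells (-0.042) and Ywhaz in mural cells (-0.016). At gene ends Ly86 (0.489, from -1.74) and Zfp36 (-0.061) reversed in endothelial cells, and 583 genes were lower in mural cells against 1162. Zfp36 and Ywhaz had passed no call. In the arterial comparison DESeq2 called 10 genes higher and 18 lower, and the fit without library block 47 lower. Of 35 list calls, 0 passed with an estimated correlation, under which 2 of 84 tests had an unadjusted p under 0.05. That repeat rests on 3 residual degrees of freedom, so it cannot tell whether correlation between genes undoes these calls. The endothelial share was 17.9% at a Leiden resolution of 1.0, and the macrophage share 17.1% with a minimum of 3000 open regions. The share of unnamed cells was 7.58% at that resolution, 4.63% with that minimum, 2.48% with doublets kept and 4.22% with centring per library. Except for the number of regions tested, the cause was not tested.

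The sides of the region counts differed between settings, of which matched depth also had fewer cells and regions. Of regions called in mural cells 57.4% were higher, against 79.6% without TMM factors, 77.5% with DESeq2, 79.9% with cells of matched depth and 50.5% with doublets kept, and in fibroblasts 74.2% against 61.5% with DESeq2. In macrophages and monocytes 55.4% were higher, against 48.4% without TMM factors and 49.4% with cells of matched depth. Housekeeping genes lay higher in endothelial cells than in fibroblasts by a difference of medians of 0.339, and by 0.301 with cells of matched depth (0.242 in replicate 1 and 0.36 in replicate 2). Mural cells were the smallest tested class, at 306 cells. The planned promoter values, motif shares, counts of cells with a region open and overlap of region lists were not run.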

Other observations

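The comparisons of clusters within fibroblasts and within macrophages, the test of cardiomyocyte markers and the 3 tests at the distal ends of X and Y were chosen after the result was seen. Clusters of fibroblasts differed in single genes. They were compared with labels from the chromosomes not tested, and no gene list was tested within fibroblasts. A cluster had 418 of 16302 genes higher and 1183 lower than the other fibroblasts (edgeR quasi-likelihood). It was summed over 301 cells in replicate 1 and 240 in replicate 2 for odd-numbered chromosomes, and 189 and 98 for the others. Both parts were scaled by 1 library total. Genes on odd-numbered chromosomes were therefore shifted up in this cluster and genes on the others down. That shift was not removed, so the counts and fold changes of this cluster are biased, and smaller changes may have the wrong direction. The cluster had raised Cps1, an enzyme of the urea cycle (32.2 CPM against 4.33, log2 fold change 2.92 ± 0.23 SE), Erbb4, a neuregulin receptor (2.56 ± 0.17), and Ano1, a chloride channel (2.21 ± 0.17). Of 12 platelet-derived and fibroblast growth factor genes 4 were higher (Pdgfa, Pdgfb, Pdgfc and Pdgfd) and 1 lower (Fgf7). Of 13 collagens 4 were lower, among them Col4a1 and Col4a2. Pdgfb, Pdgfc and Pdgfd lie on chromosomes 15, 3 and 9 and Fgf7 on chromosome 2, so their directions are those of the shift. These list counts therefore show no growth factor or collagen profile of the cluster. Of 12 mural markers 2 were higher, Tagln and Lmod1, most of whose calls are shared with a neighbour, as were 2 of 19 smooth muscle genes, Myocd and Rgs4. Of 12 fibroblast markers 2 were lower, Tcf21 and Mfap5. These marker changes carry the shift, so they cannot tell whether this cluster holds cells related to mural cells, which were not excluded. Markers of other cells moved as well, under the same shift. Lower were C1qb and Mrc1 of 9 macrophage markers, Car4 and Timp4 of 6 capillary, Pdpn of 6 lymphatic and Mmp9 of 3 granulocyte. Prf1 of 3 NK, Upk3b of 5 mesothelial and Ermap of 4 erythroid markers were lower too. Cd5 of 5 T cell and S100b of 6 Schwann markers were higher. Of 11 endothelial, 7 cardiomyocyte and 8 arterial markers 1 each was higher and 1 lower. The largest fall was in Dpp4, a cell-surface peptidase (-4.59 ± 0.28). Dpp4 was highest in another cluster (833 and 904 cells, and 852 and 927), with 103 CPM against 30.4 (2.92 ± 0.16), where Serpina16 (2.96 ± 0.26) and Il22ra2, a decoy receptor of interleukin-22 (2.42 ± 0.16), were raised too. In that cluster 396 genes were higher and 264 lower. It was compared with a mean that includes the cluster with raised Cps1. Its counts and fold changes therefore carry part of the shift in the opposite direction, down for genes on odd-numbered chromosomes and up for the others. Without replicate 2, 747 of the 1183 and 162 of the 264 lower genes had a fall of at least 1, and DESeq2 called 175 in place of the 264.

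Macrophages and monocytes held 2 clusters, a larger and a smaller (336 and 205 cells for odd-numbered chromosomes, 342 and 217 for the others). In the smaller, 11 of 15023 genes were higher and 229 lower (edgeR quasi-likelihood), and DESeq2 called 2 and 9, so these counts depend on the test. Lower genes included Cgref1 (log2 fold change -2.32 ± 0.28 SE) and Bcl2a1a, a survival gene of the BCL2 family (-2.14 ± 0.23). Of 16 chemokine and receptor genes 3 were lower (Ccl7, Cxcl14 and Ccr1), and of 12 macrophage markers 1 was lower, Cx3cr1, the fractalkine receptor. Markers of other cells were lower too: Cxcr2 of 4 granulocyte markers (median -0.68), Itgax of 6 dendritic (-0.37), Ms4a1 of 6 B cell (-0.51), Cd5 of 6 T cell (-0.36), Upk3b of 3 mesothelial (-0.34) and Fabp4 of 5 capillary markers (-0.62). Raised genes included Wdr95 (1.84 ± 0.19), Asmt at the distal end of X (1.81 ± 0.20) and the heat shock gene Hspa1b (1.09 ± 0.08).

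Myom2 and Trdn were open in fibroblasts although the sort was for non-myocytes. DNA of cardiomyocytes in these barcodes could bring such a signal and would raise other cardiomyocyte markers, of which Ryr2 (log2 fold change 2.29 ± 0.20 SE), Tnnt2 (0.81 ± 0.16) and Ttn (0.68 ± 0.17) lay higher and Actn2 (-0.37 ± 0.24) and Myl2 (-0.20 ± 0.16) did not. The median of these 5 was 0.561 (0.648 in replicate 1 and 0.475 in replicate 2), above the bound of 0.5 in 1 library and under it in the other, and far below the 5.22 of Myom2 and Trdn. That this stays open rests on leaving out Pln and Tnni3 after the first value was seen, because they share 100% and 95.3% of their calls with a neighbour, while all 7 tested markers had 0.042 and 0.197, under 0.5 in each library. Myh6, Nppa and Myl7, fixed as cardiomyocyte markers too, were not among the genes tested. Within fibroblasts Myom2 was called higher in the cluster with the highest Dpp4 and lower in the one with raised Cps1. The 7 cardiomyocyte markers had medians of -0.097 and 0.173 in these clusters. Myom2 lies on chromosome 8, so both of its calls have the direction of the shift from unequal cell numbers given above. The medians carry that shift too, so these values do not show how Myom2 differs between the clusters. Doublets with cardiomyocytes stay open too, since keeping predicted doublets dilutes any gene specific to fibroblasts (mean of Myom2 and Trdn from 5.22 to 4.65). Doublets with the other 3 classes are argued against by the low levels there. These were 0.676 CPM for Myom2 and 0.849 for Trdn, against 37.8 and 36.2 in fibroblasts. No biological explanation was tested.

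In the smaller macrophage cluster Fos (log2 fold change 0.86 ± 0.07 SE), Fosb (0.93 ± 0.07) and Hsp90aa1 (0.91 ± 0.08) lay higher at an adjusted p under 0.05 but, unlike Hspa1b, under the fold threshold, and these 4 genes were picked after their values were seen. A lower depth with values capped at 1 (a median of 6943 open regions per cell against 8392.5 in the clustering on all chromosomes) would raise housekeeping genes as well, but their median was 0.13 (0.111 and 0.15 in the 2 libraries), against 0.915 for these 4 genes. A response of the cells to dissociation and sorting could raise the other immediate early genes, whose median was 0.174 (0.111 and 0.237), between the bounds of 0 and 0.2 set before it was seen. Of the 15 genes of that list, Fos and Fosb among them, 8 were higher and 0 lower at an adjusted p under 0.05 at any fold, with Jund, most of whose calls are shared with Iqcn, at 0.74 ± 0.07, Egr1 at 0.57 ± 0.07 and Jun at 0.52 ± 0.07, so that response stays open. No biological explanation was tested.

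Of the 10 regions that ranked highest for replicate 1 over replicate 2 within each of the 3 large classes, among 50511 regions with at least 300 open calls, 8 lay at the distal ends of X and Y. A different share of cells with a Y chromosome is argued against by the rest of Y, whose largest log2 ratio in size was 0.133 in these classes, while mural cells, with 69 and 46 calls, had -0.522 (-1.06 to 0.016). A different mix of classes moves no ratio within a class, and at the distal regions outside those 10 the ratio with these classes held apart was 1.444 for Y (1.27 to 1.62) and 0.269 for X (0.163 to 0.375), against 95% ranges of -0.243 to 0.184 and -0.187 to 0.143 in 1000 random sets of autosomal regions with like calls each. For X this is narrow, since the highest random set reached 0.287 and macrophages raised the value most. They had 0.527 (0.324 to 0.729) against 0.156 (0.007 to 0.304) in fibroblasts and 0.206 (-0.027 to 0.439) in endothelial cells. Mural cells, with -0.249 (-1.13 to 0.631), were left out of that value. Clusters within a class were not held apart, so a different mix of these was not tested and stays open. Asmt, at the distal end of X, was higher in the smaller macrophage cluster. That cluster held 330 of 840 macrophages and monocytes in replicate 1 and 211 of 681 in replicate 2, in the clustering on all chromosomes. Reads placed on Y in 1 library and on X in the other would lower X in replicate 1, which the same 0.269 argues against as narrowly, while a different copy number of this sequence between animals stays open and was not tested, since the labels do not say whether the libraries come from separate animals.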
